A study of Arabidopsis thaliana with 28 samples.

How the data were processed

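The samples were Arabidopsis thaliana seedlings, either wild type (WT) or a double mutant (DM) that carries the sdg25-1 and atx1-2 alleles. SDG25 (AT5G42400) and ATX1 (AT2G31650) encode histone methyltransferases of the trithorax group. Control seedlings grew at 22 °C for 10.5 days (C0) or 11.5 days (C24). Stressed seedlings grew at 22 °C for 5 days and at 35 °C for 5.5 days, and were taken at the end of the stress (R0) or after a further 24 h at 22 °C (R24). RNA-seq covered 16 libraries in 8 groups of 2 replicates, and whole-genome bisulfite sequencing covered 12 libraries in 4 groups of 3 replicates (WT and DM at C24 and R24). Groups and replicate numbers came from the sample titles. The genotype labels count the atx1 allele number upward from sample to sample, and it was read as atx1-2 throughout, as in the design text. The labels speak of biological replicates but do not say that these were grown separately, so all p-values measure only the spread between these samples, which may be technical.

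Per the labels' protocols, RNA was extracted with Trizol, made into libraries with an Illumina TruSeq RNA kit and sequenced on an Illumina HiSeq instrument, and DNA was extracted with a QIAamp kit and made into libraries with an Accel-NGS Methyl-Seq kit. The submitters' processing notes name cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d and edgeR for the series, and also Bismark, FastQC and methylKit without versions, with the genome build TAIR10. Which tool did which step, the annotation and whether reads were assigned by strand are not given in the sources used here, so overlapping and antisense genes cannot be told apart. The deposited expression values are FPKM (fragments mapped, scaled to transcript length and library size), 1 value per gene and library for 32399 genes. Genes without signal are listed at about 0.0001 FPKM rather than 0, and this is called the floor here. The number of fragments per library is not given in the sources used here. From the spacing of the smallest FPKM values, the libraries had an estimated 80.1 to 108% of the depth of WT C0 replicate 1.

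The 4 deposited methylation tables hold, per the file headers, counts of methylated and of all cytosine calls in CG, CHG and CHH context for each of 6 samples, in windows of 100 bp that start every 50 bp. The deposited methylation level is a percent, 100 times methylated calls over all calls of a window. The deposited p-values and FDR of the windows come from a test that is not given in the sources used here, and each listed window has an FDR from the authors below 0.05. The tables are therefore a selection of windows the authors had already called, and a test on the same samples is not independent evidence for them. Windows outside the tables were not analysed here. Gene parts (promoter, exon, intron, intergenic) and coordinates are those of the tables (TAIR10). The width of a promoter is not given in the sources used here, and this annotation took the place of the 2 kb upstream that had been planned. Symbols came from an NCBI table of the TAIR10.1 assembly, which was used for names only and matched 31912 of the 32399 gene identifiers (98.5%).

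Expression was tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1). Genes with an FPKM of at least 1 in at least 2 of the 16 libraries entered (21736 genes). A single fit with a mean per group and moderated variances with a trend (8 residual and 4.27 prior degrees of freedom) gave 10 comparisons: heat against control in each genotype at both times, DM against WT in each of the 4 conditions, and the difference between genotypes in the heat response at both times. Genes with a Benjamini-Hochberg adjusted p under 0.05 were counted as changed. A log2 fold change on this scale understates the change of genes with low FPKM, and none is given where a group was at the floor in every library. FPKM is scaled to the fragments of a library, so a fall of very abundant transcripts raises the values of the others. Each list or count was therefore also computed after median-of-ratios scaling between libraries, called rescaled here, and after quantile normalization.

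Gene lists fixed before the data were examined were tested with camera in limma at a preset inter-gene correlation of 0.01, adjusted over the 23 lists of a comparison. They were small heat shock proteins, HSP70, HSP90 and HSP100 chaperones, heat shock factors, heat memory and acclimation genes, the unfolded protein response, light harvesting and Rubisco, DNA methylation and RNA-directed DNA methylation, active DNA demethylation, the trithorax group, flowering time, abscisic acid and dehydration, salicylic acid defence, jasmonate, antioxidant enzymes, anthocyanin and flavonoid synthesis, warm-temperature growth and auxin, cell cycle, leaf senescence, circadian clock, markers of root, flower and seed maturation, and ONSEN retrotransposons. Some genes stand in more than 1 list. Counts of list members are given over all genes tested and, where marked, adjusted over the list alone. Small heat shock protein paralogs, the LHCB1 and RBCS genes, the MAF genes, the cruciferins and the ONSEN copies have near-identical relatives, so the authors' assignment of reads may have split or shared their values.

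Methylation was tested per window with a quasi-binomial logistic regression on the deposited counts of the 6 samples (numpy 2.4.6, scipy 1.17.1), for windows with at least 10 calls in each sample, with Benjamini-Hochberg adjustment over the windows of a table. Neighbouring windows overlap and are not independent. Mean levels per library were compared with a two-sided exact permutation test, whose smallest p for 3 against 3 libraries is 0.1. A window was called CG only where its mean over the 6 samples was over 20% in CG, under 5% in CHG and under 3% in CHH. Windows at chromosome 2, positions 3230000 to 3630000, and windows with 3000 or more calls were also left out, a choice made after seeing the data. Overlaps used identical windows and Fisher's exact test.

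In simulated data for DM against WT at R24, 200 of 21736 genes were changed, drawn from those with a mean log2 value above 1. All groups had the same spread per gene. The expression test found 6% of the genes changed by 0.5 on the log2 scale, 64% of those changed by 1, and 100% of those changed by 2 or 3. It made 135 right calls and 12 false ones. Simulated windows with as much spread between samples as a beta precision of 30, of which 10% were changed, gave almost no calls (0.8% of differences of 30 points at most). After that result a second setting was added, with a precision of 300 and 50% changed windows. There 98.0 to 99.7% of differences of 30 points and 39.6 to 58.0% of differences of 10 points were found. Windows called in the data had median differences of 5.695 to 6.442 points, below both simulated sizes.

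The genes named in the text were chosen by a rule fixed before the data were examined: the 2 mutated genes, for each comparison the 6 largest and 6 most negative log2 fold changes among named genes past the threshold with a mean of at least 5 FPKM in the higher group and libraries that did not overlap, and members of the lists, first the 4 with the smallest adjusted p. Chance alone leaves 2 against 2 libraries without overlap in 33.3% of cases. For methylation, the rule took the 3 largest differences in each direction and windows at genes named by the other parts of the rule. The groups, tests, lists and the alternatives named first were also fixed before the data were examined; alternatives and tests added later are named as such. The alternatives were other pseudocounts, filters, scalings and thresholds, fits with fewer libraries, a replicate block, other coverage minimums, dispersions and window sets, and leaving out each library in turn. Replicate numbers were not used as a block in the values given first.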

Results

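Expression was measured in 16 seedling libraries, 2 for each combination of genotype (WT or DM) and condition (C0, C24, R0 or R24). Summed FPKM ran from 666769 to 766126 per library, and 18751 to 20060 genes reached 1 FPKM. The 10 most abundant genes held 8.85 to 11.8% of all FPKM in the control libraries and 3.05 to 5.63% in the heat-treated ones. Replicates of a group correlated at 0.967 to 0.991 (Pearson, across genes, which are not independent). WT R0 replicate 2 correlated more closely with the 2 libraries labelled DM R0 (0.9716 and 0.9713) than with WT R0 replicate 1 (0.9665). Deviations of replicate 1 from its group mean correlated at 0.511 between WT R0 and the libraries labelled DM R0. This was the highest of 28 pairs of groups, so the R0 libraries may share an effect of replicate number. DNA methylation was measured in 12 libraries, 3 for each genotype at C24 and R24, with a median of 110 to 288 cytosine calls per window and library. The design asks how seedlings respond to prolonged heat, how much of the response is left after recovery, and how both differ in a mutant of 2 histone methyltransferases. FPKM values below are the mean ± SD of 2 libraries, and log2 fold changes are given ± SE with limma adjusted p-values.

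The mutated genes were read first. SDG25 (AT5G42400) was at the floor of 0.0001 FPKM in both DM C0 libraries and both DM C24 libraries, against 4.72 and 3.98 FPKM in WT C0 and 3.69 and 2.42 FPKM in WT C24. At R24 it was at 0.00962 and 0.0555 FPKM in DM and at 5.86 and 5.10 FPKM in WT (log2 fold change -2.65 ± 0.33, limma adjusted p = 2.7e-04). The libraries labelled DM R0 held 1.62 and 3.81 FPKM of SDG25, against 2.18 and 6.03 FPKM in WT R0 (log2 fold change -0.41 ± 0.33, limma adjusted p = 0.403). ATX1 (AT2G31650) was at 1.15 and 1.51 FPKM in DM C0, 1.63 and 1.22 in DM C24 and 0.957 and 1.07 in DM R24, against 2.89 and 3.28, 2.38 and 2.52, and 4.34 and 3.65 in the matching WT libraries. Its fall passed the test at R24 (log2 fold change -1.31, limma adjusted p = 0.00616, and 0.0615 without WT R24 replicate 1) and not at C0 or C24 (log2 fold changes -0.81 and -0.51). The libraries labelled DM R0 held 2.34 and 5.81 FPKM of ATX1, against 2.95 and 4.83 FPKM in WT R0. Transcript of both mutated genes at about the WT level puts the label of these libraries in question. They are therefore called the libraries labelled DM R0 throughout, and every direction drawn from them rests on that label. Genes called lower in DM at both control times stayed below WT R0 in these libraries, as weighed further below. The floral repressor FLC (AT5G10140) was low in them as in the other DM libraries (0.734 and 0.640 FPKM, against 6.73 and 5.71 in WT R0). Which part of each transcript the mutations remove is not given in the sources used here.

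**Figure D1:**
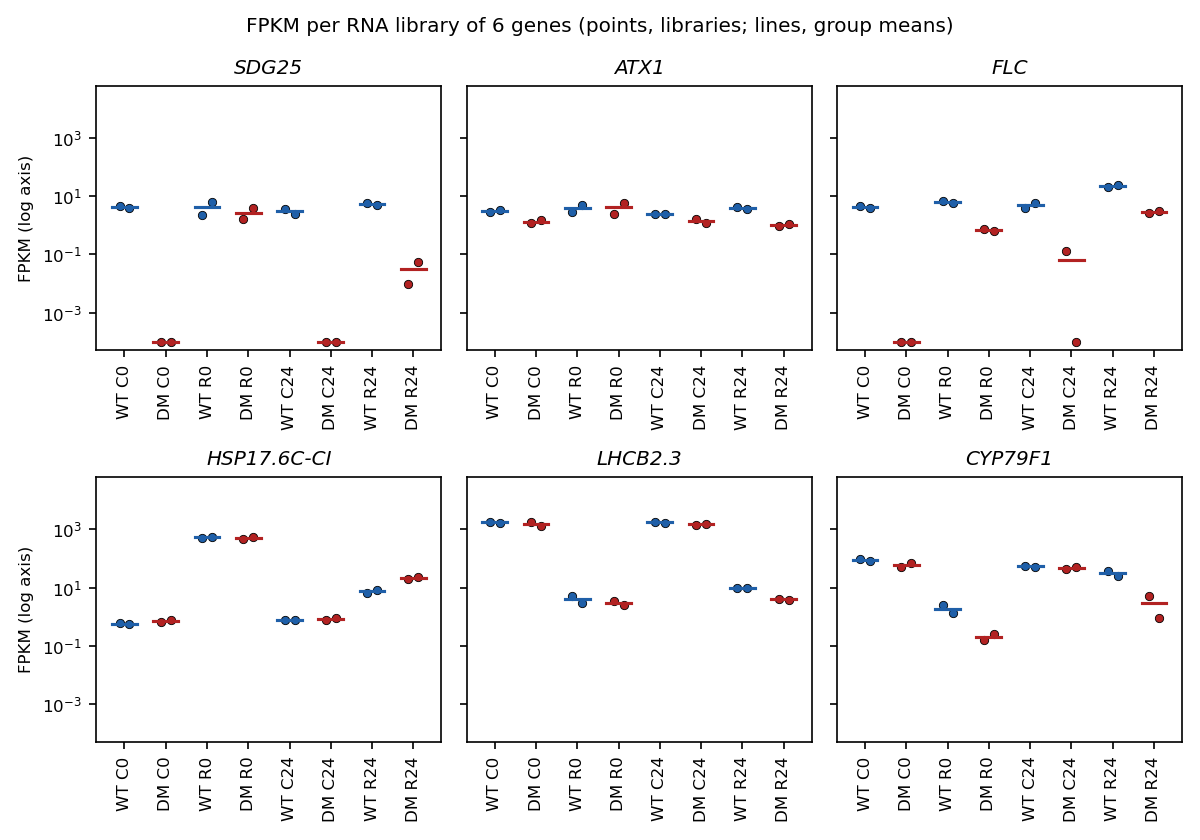
FPKM of 6 genes in each RNA-seq library on a log axis; points are libraries and lines are group means. SDG25 is at the floor of 0.0001 FPKM in 4 DM control libraries and at 1.62 and 3.81 FPKM in the libraries labelled DM R0.

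At the end of the heat stress in WT (R0 against C0), transcripts of small heat shock proteins, chaperones that hold unfolding proteins, rose the most. HSP17.6A (AT5G12030) rose from 0.892 ± 0.132 to 767 ± 324 FPKM (log2 fold change 8.60 ± 0.30, limma adjusted p = 2.7e-10, n = 2 libraries per group). HSP17.6II, HSP17.6C-CI, HSP23.6, HSP17.4A and HSP22 reached 686, 541, 398, 618 and 298 FPKM, with log2 fold changes between 7.91 and 8.54. Those that fell the most were 4 light harvesting genes, a carbonic anhydrase and an aldolase. LHCB2.3 (AT3G27690), a chlorophyll-binding protein of photosystem II, fell from 1723 ± 175 to 3.91 ± 1.46 FPKM (log2 fold change -8.48 ± 0.20, limma adjusted p = 1.6e-11). LHCB1.4, LHCB1.2 and LHCB1.3, near-identical copies whose single values are uncertain, had log2 fold changes of -7.91, -7.68 and -6.19. The carbonic anhydrase CA1 fell from 2344 to 26.1 FPKM (-6.47) and the aldolase FBA5 from 218 to 0.711 FPKM (-7.02).

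By list, 15 of 16 small heat shock proteins rose and 0 fell, with a median log2 fold change of 7.08 (camera adjusted p = 4.3e-07; adjusted p = 0.50 with an estimated correlation). Of the 18 heat memory and acclimation genes 16 rose, among them the peroxidase APX2 (7.87), MBF1C (4.84) and DREB2A (3.91), at camera adjusted p = 2.4e-05 (adjusted p = 0.532 with an estimated correlation). Of 18 heat shock factors 13 rose and 1 fell (14 and 1 adjusted over the list alone), led by HSFA3 (4.70) and HSFA2 (3.68), at camera adjusted p = 0.0263 (adjusted p = 0.557 with an estimated correlation). All 8 ONSEN copies, heat-activated retrotransposons, rose, with a median of 4.43 (camera adjusted p = 0.0254; adjusted p = 0.666 with an estimated correlation). The unfolded protein response list had 8 of 12 members higher, such as ERDJ3A (3.74) and NAC103 (3.14), at camera adjusted p = 0.0491; adjusted p = 0.557 with an estimated correlation, and 0.171 rescaled. All 25 light harvesting and Rubisco genes fell (median -4.80, camera adjusted p = 3.7e-17; adjusted p = 0.50 with an estimated correlation). Of 16 cell cycle genes 13 fell and 0 rose, for example the mitotic cyclin CYCB1-2 (-2.71), at camera adjusted p = 5.4e-06 (adjusted p = 0.50 with an estimated correlation). Of 10 root markers 7 fell, led by the iron transporter IRT1 (-4.34), at camera adjusted p = 0.00444 (adjusted p = 0.50 with an estimated correlation). Of 8 active demethylation genes 4 fell and 1 rose; the DNA glycosylase ROS1 went from 11.7 to 0.619 FPKM (-2.97), at camera adjusted p = 0.0416 for the list (adjusted p = 0.590 with an estimated correlation). Of 12 anthocyanin and flavonoid genes 7 fell, such as FLS1 (-2.95), and 2 rose, at camera adjusted p = 0.0416; adjusted p = 0.666 with an estimated correlation, and 0.116 rescaled.

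The other lists did not pass camera in this comparison. Members rose and fell as follows: HSP70, HSP90 and HSP100 chaperones 12 and 3 of 18 (HSP90.1 5.90, HSP101 3.01, HSC70-1 -0.98), abscisic acid and dehydration 13 and 1 of 19, salicylic acid defence 11 and 2 of 16, jasmonate 8 and 1 of 14. Antioxidant enzymes had 9 higher and 4 lower of 13, the circadian clock 7 and 2 of 11, leaf senescence 5 and 3 of 8, warm-temperature growth 4 and 5 of 10 (PIF4 -2.59) and flower markers 2 and 0 of 2. The DNA methylation list had 9 higher and 13 lower of 30 (CLSY1 1.69, MET1 -1.59). Trithorax genes (4 and 1 of 13) and flowering-time genes (3 and 2 of 10) had medians of 0.14 each as deposited and of -0.27 and -0.28 rescaled, and camera gave both a negative direction. None of 6 seed maturation markers passed the limma test (medians 0.05 as deposited and 0.04 rescaled).

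In all, 16067 of 21736 genes changed in this comparison (limma, adjusted p under 0.05), 10760 higher and 5307 lower. The median log2 fold change of all genes was 0.40, and rescaling lowered it by 0.37, so the gene values above include a general upward shift of that size. Rescaled, 7815 genes were higher and 7516 lower. Relative to the shift, the list medians were 6.75 for small heat shock proteins, 3.49 for heat memory genes, 0.69 for heat shock factors, 0.30 for the unfolded protein response, -5.25 for light harvesting and -1.42 for the cell cycle, with no change of sign.

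The libraries labelled DM R0, set against DM C0, showed the same leading groups. HSP17.4A rose from 0.867 ± 0.328 to 647.1 ± 90.12 FPKM (log2 fold change 8.44 ± 0.22, limma adjusted p = 3.2e-11), with HSP17.6A, HSP17.6C-CI, HSP17.6II and HSP23.6 between 7.73 and 8.25. The lipid transfer protein LTP4 rose from 0.909 to 419 FPKM (7.79). LHCB2.3 fell from 1525 ± 341 to 2.94 ± 0.656 FPKM (log2 fold change -8.59 ± 0.20, limma adjusted p = 1.1e-11), followed by LHCB1.2 (-8.42), LHCB1.4 (-8.24), CA1 (-7.52), the Rubisco small subunit gene RBCS1B (-7.42) and LHCB1.1 (-7.22). Small heat shock proteins (15 of 16 higher, 1 lower), heat memory genes (16 of 18 higher), heat shock factors (14 of 18 higher, 2 lower) and ONSEN copies (8 of 8 higher) passed camera upward at adjusted p = 1.7e-06, 5.7e-06, 0.0239 and 0.00846. With an estimated correlation their adjusted p were 0.492, 0.547, 0.586 and 0.586. Light harvesting (25 of 25 lower), the cell cycle (16 of 16 lower) and root markers (6 of 10 lower, 2 higher) passed downward at camera adjusted p = 7.5e-16, 6.5e-07 and 0.0308; with an estimated correlation the adjusted p were 0.492, 0.492 and 0.586, and rescaled the root list was at 0.0583.

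In that comparison 16391 genes changed (limma), 10236 higher and 6155 lower, with a median shift of 0.29 by rescaling, after which 8041 were higher and 7747 lower. Of the genes called in both genotypes, 14069 of 14147 went the same way (9228 higher and 4841 lower in both, where independent lists would share 5067 and 1503). Rescaled list medians were 5.85 for small heat shock proteins, 5.24 for ONSEN, 3.74 for heat memory genes, -6.34 for light harvesting and -1.60 for the cell cycle.

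After 24 h of recovery in WT (R24 against C24), the largest increase was that of GPT2 (AT1G61800), a plastid glucose 6-phosphate transporter, from 1.52 ± 0.42 to 409.6 ± 64.5 FPKM (log2 fold change 7.35 ± 0.32, limma adjusted p = 4.9e-09, n = 2 libraries per group). The ribonuclease RNS1 (6.28), the transcription factor NAC019 (6.16), DXPS1 (5.78), the alcohol dehydrogenase ELI3-2 (5.71) and DIP2 (5.65) followed. LHCB2.3 was still low, at 9.81 ± 0.295 FPKM against 1718 ± 11.7 FPKM (log2 fold change -7.31 ± 0.20, limma adjusted p = 5.6e-10), as were LHCB1.4 (-6.31) and CA1 (-5.34). ECS1 fell from 619 to 10.5 FPKM (-5.81), PCC1 by a log2 fold change of -5.71 and the germin-like gene GER3 by -5.66.

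Abscisic acid and dehydration genes were higher in 17 of 19 cases and lower in 1, with the phosphatase gene HAI1 at 5.35, LEA4-5 at 5.10 and RD29A at 4.47 (camera adjusted p = 0.00977; adjusted p = 0.897 with an estimated correlation). Of the small heat shock proteins 10 of 16 were higher and 2 lower, with HSP17.4A at 2.80 and HSP17.6C-CI at 2.27 (list median 1.28, camera adjusted p = 0.337). Of the heat memory genes 9 of 18 were higher and 2 lower; HSFA3 (2.11) and DREB2B (2.16) were among the higher ones and HSFA2 (-0.95) and GOLS1 (-0.64) the lower ones, which lost their calls without WT C24 replicate 2 (adjusted p = 0.0663 and 0.0699). All 25 light harvesting genes were lower (median -4.10, camera adjusted p = 3.3e-21; adjusted p = 0.606 with an estimated correlation). Of 16 cell cycle genes 12 were lower and 1, CYCB1-1 (1.52), was higher (camera adjusted p = 5.6e-05; adjusted p = 0.628 with an estimated correlation). Warm-temperature growth genes were lower in 5 of 10 cases and higher in 2 (camera adjusted p = 0.0154; adjusted p = 0.319 with an estimated correlation, and 0.0839 rescaled). ONSEN copies were higher in 7 of 8 cases (median 2.45, camera adjusted p = 0.279, and 0.0341 rescaled). The floral repressor FLC rose from 4.8 ± 1.09 to 21.6 ± 2.27 FPKM (1.97). ROS1 stayed low (-2.88).

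Here 15203 genes changed (limma), 11129 higher and 4074 lower. Rescaling lowered the median of all genes by 0.42 and gave 6444 higher and 6592 lower. Rescaled list medians were 2.11 for abscisic acid, 1.04 for small heat shock proteins, -4.62 for light harvesting and -1.303 for the cell cycle. For several lists that did not pass camera the median changed sign on rescaling: 0.16 to -0.34 for HSP70, HSP90 and HSP100 chaperones, 0.23 to -0.10 for DNA methylation, 0.26 to -0.23 for jasmonate and 0.16 to -0.19 for salicylic acid defence.

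In DM the same comparison (R24 against C24) gave ELI3-2 as the largest increase, from 0.832 ± 0.047 to 368 ± 27.9 FPKM (log2 fold change 7.65 ± 0.24, limma adjusted p = 2.5e-10), then GPT2 (6.97), NAC019 (6.90), the cytochrome P450 CYP76C2 (6.75), the nitrate transporter NRT1.8 (6.67) and DXPS1 (6.52). LHCB2.3 (-8.23), ECS1 (-7.72), CA1 (-7.71), GER3 (-7.46), LHCB1.4 (-7.43) and CA2 (-7.24) had the largest decreases; CA2 fell from 730.3 ± 9.39 to 3.83 ± 0.239 FPKM (limma adjusted p = 4.5e-11). Lists that passed camera were light harvesting (25 of 25 lower), the cell cycle (13 of 16 lower, 1 higher), abscisic acid (16 of 19 higher, 2 lower), active demethylation (5 of 8 lower) and warm-temperature growth (7 of 10 lower, 2 higher), at adjusted p = 6.7e-18, 5.6e-06, 0.0275, 0.0366 and 0.0457. With an estimated correlation their adjusted p were 0.541, 0.541, 0.883, 0.883 and 0.541, and warm-temperature growth was at 0.105 rescaled. Small heat shock proteins were higher in 12 of 16 cases and lower in 2 (median 1.70; camera adjusted p = 0.0623, and 0.0159 rescaled). The antioxidant list had a median of 1.02 while camera gave a negative direction (adjusted p = 0.967). In all 15229 genes changed (limma), 9989 higher and 5240 lower, with a shift of 0.30 by rescaling, after which 7160 were higher and 6954 lower. Of the genes called in both genotypes at this time, 12895 of 12958 went the same way.

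**Figure D2:**
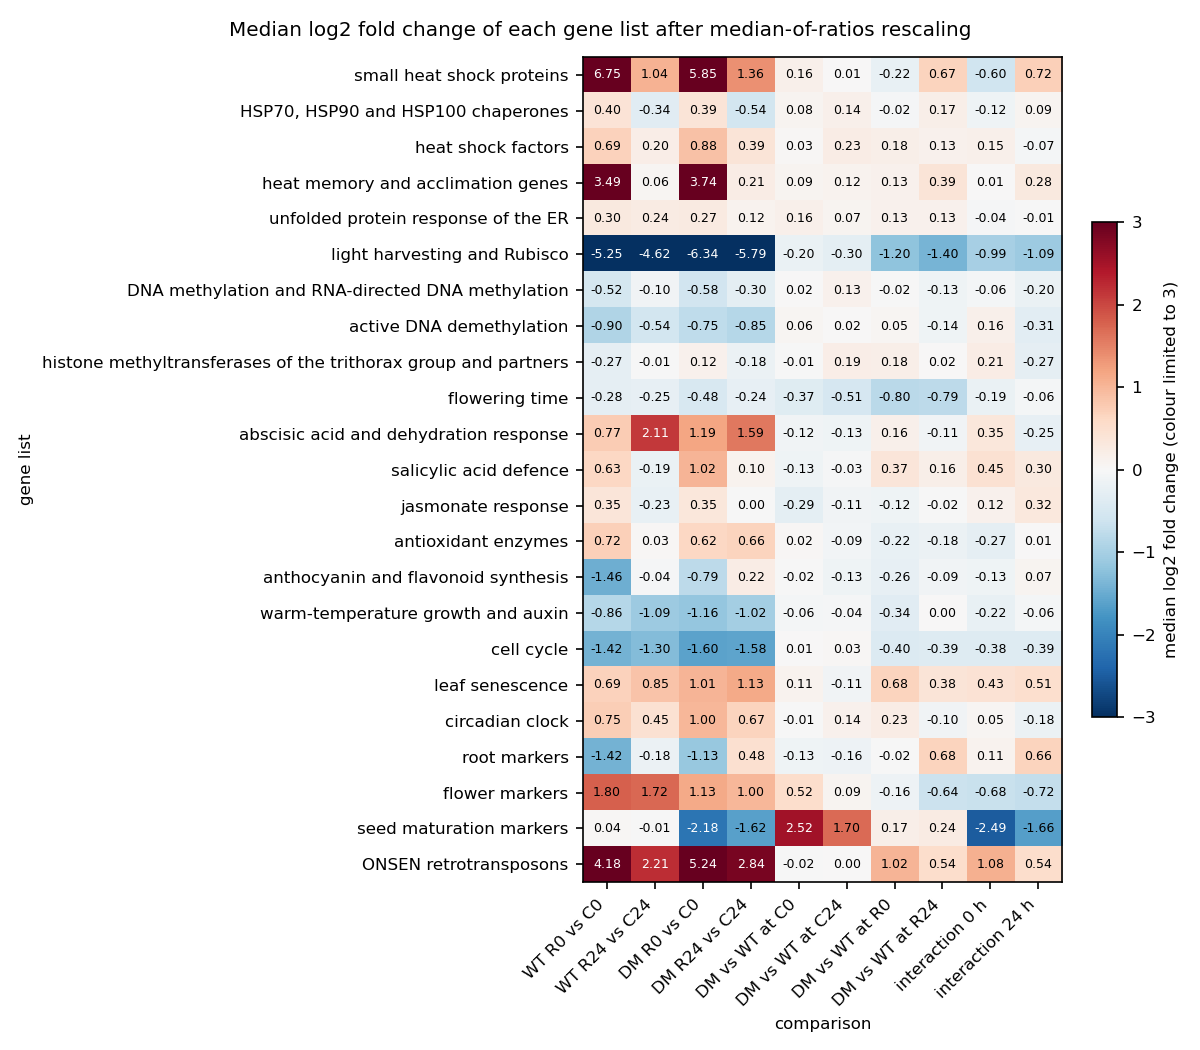
Median log2 fold change of each of 23 gene lists (vertical) in each of 10 comparisons (horizontal), from rescaled values; colours are limited to 3 in either direction and the numbers give the medians. Light harvesting is at -5.25 in WT and -6.34 in the libraries labelled DM R0 at the end of the stress. After recovery it is at -4.62 in WT and -5.79 in DM.

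Without heat, DM differed from WT in few genes. MRD1 (AT1G53480) was at 0.62 ± 0.331 FPKM in DM and 20.2 ± 0.257 FPKM in WT at C0 (log2 fold change -3.73 ± 0.24, limma adjusted p = 3.3e-05) and at 2.33 and 27 FPKM at C24 (-3.09). Among floral repressors of the MADS-box family, FLC was at the floor in both DM C0 libraries against 4.35 ± 0.533 FPKM in WT (limma adjusted p = 3.3e-05) and at 0.0641 against 4.8 FPKM at C24 (-2.44). FLM was lower at both times (-1.73 and -1.59), as was MAF5 (-2.02 and -2.30), and MAF4 was lower at C24 (-1.65). The MAF genes share sequence with each other. The retroposon SADHU3-2 was lower at both times (-2.66 and -2.13), and the disease resistance gene TAO1 at C0 (-1.62). The floral activator SOC1 was higher in DM at C0, at 33.2 ± 1.03 against 16.4 ± 0.0307 FPKM (0.97, limma adjusted p = 0.0203). The seed storage protein gene CRU3 was at 9.99 and 20.4 FPKM in DM C0 and at the floor in both WT C0 libraries (limma adjusted p = 0.022).

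The flowering-time list was lower in DM by camera at C0 (1 higher and 3 lower of 10, 2 and 5 adjusted over the list alone, adjusted p = 6.9e-08) and at C24 (0 higher and 4 lower, 2 and 5 adjusted over the list alone, adjusted p = 2.4e-08). With an estimated correlation these were at adjusted p = 0.0260 and 0.0192. Together with the same list at R24, they were the only ones of 66 called lists, among 230 tests, that held with an estimated correlation. Seed maturation markers were higher at C0 (1 of 6, and 6 of 6 adjusted over the list alone; camera adjusted p = 2.4e-16; adjusted p = 0.0503 with an estimated correlation). At C24 their medians stayed positive, with 0 members past the limma test and 3 adjusted over the list alone (camera adjusted p = 4.5e-06; adjusted p = 0.469 with an estimated correlation). Other lists passed camera with 0 members past the limma test and small medians, among them the unfolded protein response at C0 (median 0.22, camera adjusted p = 2.4e-06; adjusted p = 0.104 with an estimated correlation) and light harvesting at C24 (median -0.21, camera adjusted p = 0.000225; adjusted p = 0.698 with an estimated correlation).

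In all, 16 genes differed at C0 (8 higher and 8 lower in DM, limma) and 15 at C24 (6 higher, 9 lower); 9 were shared and all of these went the same way. Rescaled, the splits were 11 and 12 at C0 and 8 and 20 at C24. At an unadjusted p under 0.05 there were 898 and 1390 genes. With only the libraries compared in the limma fit, 0 genes passed at either time, and the genes named here were at adjusted p = 0.168 to 0.719 (C0) and 0.368 to 0.559 (C24) with the same fold changes. The count at C0 fell to 9 without DM C0 replicate 2, 8 without WT C0 replicate 1 and 9 without WT C0 replicate 2. CRU3, SOC1 and TAO1 lost their calls at C0 without any single library of the comparison (adjusted p of 0.0607 to 0.224), MAF5 at C0 without WT C0 replicate 1 (0.0844) or DM C0 replicate 2 (0.0592), SADHU3-2 at C24 without WT C24 replicate 1 (0.143), DM C24 replicate 1 (0.0760) or DM C24 replicate 2 (0.0833), and MAF4 at C24 without WT C24 replicate 2 (0.106) or DM C24 replicate 1 (0.0746).

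At the end of the heat stress, the directions between the libraries labelled DM R0 and WT R0 rest on the label of libraries that held transcript of both mutated genes. The dark-induced glucosidase DIN2 (AT3G60140) was at 34.9 ± 2.81 FPKM in them and 3.49 ± 2.65 FPKM in WT R0 (log2 fold change 3.14 ± 0.31, limma adjusted p = 1.7e-04, n = 2 libraries per group). The polygalacturonase ADPG1 (2.54), the defensin LCR67 (2.23), the glucosidase BGLU28 (2.203), the kinase MAPKKK18 (2.19) and the transporter ABCG40 (2.11) were also higher. RPB5C, a subunit of RNA polymerase II, was at 1.36 ± 0.0777 against 12.7 ± 0.558 FPKM (log2 fold change -2.53 ± 0.26, limma adjusted p = 2.0e-04). BCAT4 (-2.50) and MAM1 (-2.37), which extend methionine for glucosinolate synthesis, NdhL (-2.42), RBCS2B (-2.33) and RBCS1B (-2.31) were lower.

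By list, 19 of 25 light harvesting genes were lower (23 adjusted over the list alone; median -1.25, camera adjusted p = 3.1e-08; adjusted p = 0.755 with an estimated correlation). Of 10 flowering-time genes 7 were lower (8 adjusted over the list alone), including FLC (-2.09), MAF5 (-1.77) and SVP (-0.99), at camera adjusted p = 5.6e-06 (adjusted p = 0.0621 with an estimated correlation). Of 16 cell cycle genes 8 were lower (9 adjusted over the list alone), such as KNOLLE (-1.16), at camera adjusted p = 0.00418 (adjusted p = 0.755 with an estimated correlation). Salicylic acid defence (2 of 16 higher: PR5 1.296 and WRKY38 0.84) and leaf senescence (2 of 8 higher: SAG13 1.38 and ORE1 1.08) passed camera upward at adjusted p = 0.0143 and 0.0228; adjusted p = 0.755 for both with an estimated correlation. The ONSEN list passed upward with 0 copies past the limma test (median 0.99, camera adjusted p = 0.0143; adjusted p = 0.816 with an estimated correlation). Of the small heat shock proteins 4 of 16 were lower, among them HSP21 of the chloroplast (-1.25) and HSP17.6II (-0.85), and the list did not pass (camera adjusted p = 0.183). The jasmonate list had a median of -0.14 while camera gave a positive direction (adjusted p = 0.959).

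In all 4438 genes differed (limma), 1429 higher and 3009 lower. Rescaled, 1671 were higher and 2371 lower. With replicate number as a block, which fits 1 effect shared by all groups, 4312 of the 4438 genes kept their calls. An effect of replicate number particular to R0 was not fitted. With only the WT R0 libraries and those labelled DM R0 in the limma fit, 0 genes passed (4113 at an unadjusted p under 0.05). Every gene called above then lost its call, at adjusted p = 0.143 (DIN2, RPB5C and FLC among others) to 0.294 (WRKY38), with the same fold changes. The count was 8316 without WT R0 replicate 2, 2594 without WT R0 replicate 1 and 1659 without DM R0 replicate 2. Calls were lost for RBCS1B without DM R0 replicate 2 (adjusted p = 0.0665), HSP17.6II without DM R0 replicate 1 (0.0917), HSP21 without DM R0 replicate 1 (0.0945) or WT R0 replicate 2 (0.0518, log2 fold change -0.77) and WRKY38 without WT R0 replicate 1 (0.134) or DM R0 replicate 2 (0.244, log2 fold change 0.35). SAG13 lost its call without WT R0 replicate 1 (0.157), DM R0 replicate 1 (0.139) or DM R0 replicate 2 (0.0896), and ORE1 without any single library of the comparison (0.0522 to 0.131).

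After recovery (R24), HO4 (AT1G58300), a heme oxygenase, was at 8.57 ± 0.554 FPKM in DM and 0.425 ± 0.232 FPKM in WT (log2 fold change 2.76 ± 0.15, limma adjusted p = 2.9e-06, n = 2 libraries per group). CYP94B3, which oxidises jasmonoyl-isoleucine, was at 94.7 ± 34.9 against 21.1 ± 1.73 FPKM (2.06, limma adjusted p = 2.9e-04), and ELI3-2 (1.91) and CYP71A12 (1.83) were also higher. ICL and MLS, enzymes of the glyoxylate cycle, had log2 fold changes of 2.09 ± 0.60 and 1.87 ± 0.50, with ICL at 77.6 ± 78.8 FPKM in DM. The lowest gene in DM was CYP79F1 (AT1G16410), at 2.94 ± 2.85 against 31.5 ± 8.9 FPKM (log2 fold change -3.23 ± 0.39, limma adjusted p = 2.1e-04). The aspartate kinase AK3 (-3.20), the glutathione transferase GSTU20 (-3.08), BCAT4 (-3.06), RBCS1B (-2.97) and MAM1 (-2.94) followed. CYP79F1, BCAT4 and MAM1 make aliphatic glucosinolates, the methionine-derived defence compounds of this plant family.

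Of 25 light harvesting genes 24 were lower in DM at R24 (25 adjusted over the list alone; median -1.46, camera adjusted p = 2.9e-13; adjusted p = 0.553 with an estimated correlation). Small heat shock proteins were higher in 7 of 16 cases (9 adjusted over the list alone) and lower in 0, with HSP17.6C-CI at 1.396, HSP17.8 at 1.33, HSP17.4A at 1.28 and HSP17.6A at 1.18 (camera adjusted p = 6.7e-06; adjusted p = 0.534 with an estimated correlation). The heat memory list passed upward with 1 of 18 members past the limma test and 0 adjusted over the list alone (camera adjusted p = 0.00809; adjusted p = 0.739 with an estimated correlation). Of 10 flowering-time genes 8 were lower (9 adjusted over the list alone), both repressors such as FLC (-2.52) and FLM (-1.28) and the activators FT (-1.05) and SOC1 (-0.72), at camera adjusted p = 1.6e-06 (adjusted p = 0.0476 with an estimated correlation). Cell cycle genes were lower in 5 of 16 cases (10 adjusted over the list alone; camera adjusted p = 0.000181; adjusted p = 0.553 with an estimated correlation), and root markers higher in 2 of 10 (PYK10 0.75 and NRT2.1 0.88; 5 adjusted over the list alone; camera adjusted p = 0.00789; adjusted p = 0.553 with an estimated correlation). Of the abscisic acid list 4 of 19 were lower (COR15B -1.88, COR47 -1.32, ERD10 -0.93 and KIN2 -0.78) without a camera call (adjusted p = 0.211). The jasmonate repressors JAZ8 (1.58; adjusted p = 0.148 with a pseudocount of 0.1) and JAZ1 (0.99) were higher and the chaperone BIP3 of the endoplasmic reticulum was higher (1.38). The clock list had a median of -0.16 while camera gave a positive direction (adjusted p = 0.398).

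In all 3647 genes differed at R24 (limma), 1116 higher and 2531 lower; rescaled 1290 and 2101, and after quantile normalization 1722 and 2070. Of the genes called at both R0 and R24, 2106 of 2117 went the same way. The count was 2364 without WT R24 replicate 2, 1663 without WT R24 replicate 1, 1872 without DM R24 replicate 2 and 2038 without DM R24 replicate 1. With only the R24 libraries in the limma fit, ICL, MLS and ERD10 lost their calls (adjusted p = 0.127, 0.12 and 0.0552). Without DM R24 replicate 2 the log2 fold changes of ICL and MLS were 0.81 and 0.77 (adjusted p = 0.265 and 0.134), without WT R24 replicate 1 ICL, MLS and CYP71A12 were at adjusted p = 0.136, 0.0918 and 0.0982, without WT R24 replicate 2 at 0.123, 0.110 and 0.112, and CYP71A12 was at 0.155 without DM R24 replicate 1 and 0.0614 without DM R24 replicate 2. Without WT R24 replicate 1 the calls of HSP17.6A (adjusted p = 0.162), ERD10 (0.127), KIN2 (0.0673), NRT2.1 (0.0644) and SOC1 (0.0507) were lost. Without DM R24 replicate 2 those of HSP17.6A (0.0665), HSP17.8 (0.0519), ERD10 (0.125), KIN2 (0.124) and NRT2.1 (0.0626) were lost, as was HSP17.6A without DM R24 replicate 1 (0.106) and KIN2 without WT R24 replicate 2 (0.0680). FT (0.05 to 0.188) and PYK10 (0.114 to 0.221) lost their calls without any single library of the comparison.

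The heat response itself differed between genotypes. At 0 h the difference was positive for DIN2 (2.99 ± 0.43, limma adjusted p = 0.00751) and ABCG31 (2.31) and negative for NdhL (-2.36 ± 0.25, limma adjusted p = 0.0033), RPB5C (-2.44), the boron channel NIP6;1 (-2.31) and the microRNA gene MIR835 (-2.27). The response was more negative in the libraries labelled DM R0 for the flowering genes SOC1 (-1.55), SVP (-1.03) and FT (-1.75). Calls for GSTU12 (2.56), ABCG40 (2.29), BGLU28 (2.24) and MYB28 (-2.65) depended on single libraries. GSTU12 lost its call without WT C0 replicate 1, DM C0 replicate 1 or DM R0 replicate 1 (adjusted p of 0.0592 to 0.0907), ABCG40 without WT C0 replicate 1 or 2, WT R0 replicate 1 or DM C0 replicate 1 (0.0521 to 0.0795), and BGLU28 without WT C0 replicate 1 or 2, DM C0 replicate 1 or DM R0 replicate 2 (0.0622 to 0.0765). MYB28 (0.0510 to 0.126, and 0.0515 rescaled) and FT (0.0616 to 0.12) lost theirs without WT C0 replicate 1 or 2, WT R0 replicate 1, DM C0 replicate 1 or 2 or DM R0 replicate 2. In all 1277 genes passed (limma; 336 positive and 941 negative; rescaled 365 and 386). With only the libraries compared in the limma fit, 0 passed (3754 at an unadjusted p under 0.05), and the genes named for this time were at adjusted p = 0.0769 to 0.14. The count was 123, 245, 734 and 5644 without WT C0 replicate 1 or 2 or WT R0 replicate 1 or 2, and 233 and 217 without DM C0 replicate 1 or DM R0 replicate 2.

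At 24 h the difference was positive for HO4, which was at the floor in both DM C24 libraries (limma adjusted p = 5.9e-05), CYP94B3 (2.12 ± 0.37, limma adjusted p = 0.00711) and ELI3-2 (1.94), and negative for AK3 (-3.04 ± 0.49, limma adjusted p = 0.00491), CYP79F1 (-3.03), the glucosinolate regulator MYB29 (-2.86) and FBA5 (-2.76). Calls for GSTU2 (1.88), sks9 (1.81), JRG21 (1.802), MAM1 (-2.81) and BCAT4 (-2.78) depended on single libraries. GSTU2 (adjusted p of 0.0504 to 0.0824) and sks9 (0.0691 to 0.102) lost their calls without WT C24 replicate 1, WT R24 replicate 1 or DM R24 replicate 1 or 2, and also without DM C24 replicate 2 for GSTU2 and DM C24 replicate 1 for sks9. JRG21 lost its call without any WT library of the comparison or without DM C24 replicate 1 or DM R24 replicate 1 (0.0661 to 0.128). MAM1 (0.0518 to 0.0982) and BCAT4 (0.0518 to 0.0951) lost theirs without any single C24 library or without WT R24 replicate 1. The light harvesting list was more negative in DM (9 of 25 negative, 20 adjusted over the list alone, 2 rescaled; median -1.24, camera adjusted p = 4.95e-08; adjusted p = 0.928 with an estimated correlation). In all 1521 genes passed (limma; 292 positive and 1229 negative; rescaled, with a shift of the median by -0.13, 392 and 696). The count was 448 and 575 without WT R24 replicate 1 or WT C24 replicate 2, 725 and 713 without DM R24 replicate 1 or 2, and 532 and 882 without DM C24 replicate 1 or 2.

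Genes higher in WT at both R0 and R24, called memory genes here, numbered 8457; they include GPT2, NAC019, HSP17.6C-CI, APX2 and DREB2A. In DM against WT at R24, 383 of them were lower (4.53%) and 718 higher (8.49%), against 16.2% and 3.00% of the other genes. The median difference in their heat response at 24 h was -0.04, and camera ranked them above the other genes (p = 2.7e-05; p = 0.0817 with an estimated correlation). With the set chosen on DM libraries instead, including those labelled DM R0 (7952 genes), 199 were lower and 900 higher. The WT R24 or DM R24 libraries serve both to choose the genes and in the comparison, so neither split is independent of the selection. Rescaled, WT memory genes numbered 4729, of which 179 were lower and 655 higher in DM. Without DM R24 replicate 1 or 2, or WT R24 replicate 1 or 2, the number lower was 225, 145, 151 and 220, and without WT R0 replicate 1 it was 616.

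Methylation was compared between genotypes at C24 first. The window with the largest gain in DM lay in an exon of KTF1, a factor of RNA-directed DNA methylation (chromosome 5, 1202001 to 1202100), at 50.7 ± 18.1% in DM against 0.640 ± 0.560% in WT (SD, n = 3, 49 to 209 calls per library, quasi-binomial adjusted p = 0.0108). Windows in AT5G07505 (chromosome 5, 2374351 to 2374450; 49.5 ± 9.38% against 0.647 ± 0.564%) and in an exon of MRD1, also the promoter of HEI10 (chromosome 1, 19963401 to 19963500; 48.1 ± 7.30% against 2.28 ± 1.07%), gained as well, and 22 exon windows of MRD1 were higher. The largest losses were in the promoter of AT5G65165 (chromosome 5, 26037751 to 26037850; 4.17 ± 6.82% against 74.5 ± 4.69%), an intergenic window (chromosome 4, 6879651 to 6879750; 8.18 ± 7.43% against 74.5 ± 5.75%) and the promoter of AT5G23100 (chromosome 5, 7753001 to 7753100; 1.82 ± 2.35% against 65.2 ± 4.71%). The mutated genes themselves carried more methylation in DM: in ATX1 21 of 30 called exon windows were higher (chromosome 2, 13458051 to 13458150, at 28.8 ± 5.51% against 0.188 ± 0.326%), and in SDG25 45 of 56 (chromosome 5, 16958801 to 16958900, at 24.2 ± 1.69% against 3.09 ± 1.16%). FLC had 1 called window, lower in its promoter (chromosome 5, 3180251 to 3180350; 16.1 ± 7.10% against 27.4 ± 1.25%).

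Called windows at C24 were common: 15898 of the 21736 genes tested for expression had 1 or more, and the list counts below were not tested against that share. Of 30 DNA methylation genes 29 had a called window, 2 with higher windows only, 2 with lower only and 25 with both. The promoter of NRPD2, a subunit of the RNA polymerases of that pathway, was lower in 7 windows (chromosome 3, 8574601 to 8574700; 0.128 ± 0.221% against 61.5 ± 14.4%), and so was that of VIM3 in 6 (chromosome 5, 15841051 to 15841150; 2.53 ± 1.72% against 50.2 ± 5.28%). Of 11 flowering-time genes 8 had a called window (2 higher only, 5 lower only, 1 both), and all 8 ONSEN copies had lower windows. In all 91271 of 197860 tested windows passed (36768 higher, 54503 lower in DM; quasi-binomial, adjusted p under 0.05). The splits were 3968 and 13975 with at least 10 points, 103 and 482 with the stricter threshold and 10130 and 13123 with replicate number as a block, and the authors' own calls were 49713 higher and 148707 lower. Windows methylated in CG only made up 50193 of the 198420 deposited and split evenly (21124 higher, 20730 lower), 77.8% of them in exons. The others went down more often (15644 higher, 33773 lower), most of all in promoters (2288 higher, 12206 lower). The count was 49547, 52587 and 53685 without DM C24 replicates 1 to 3, and 55595 and 59060 without WT C24 replicates 1 and 3.

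At R24, the largest gains in DM were at AT1G67626 (chromosome 1, 25344001 to 25344100; 57.4 ± 3.27% against 9.17 ± 8.46%, n = 3, quasi-binomial adjusted p = 0.00522), AT3G27860 (chromosome 3, 10327001 to 10327100; 48.9 ± 3.22% against 0.841 ± 0.741%) and the promoter of AT3G13270 (chromosome 3, 4288551 to 4288650; 48.2 ± 8.92% against 2.102 ± 3.64%). The largest losses were in an intergenic window (chromosome 1, 15090551 to 15090650; 31.4 ± 2.43% against 87.3 ± 11.1%), the promoter of SKP1, a subunit of ubiquitin ligases (chromosome 1, 28515101 to 28515200; 0.436 ± 0.407% against 53.1 ± 12.0%), and another intergenic window (chromosome 4, 6428651 to 6428750; 12.6 ± 7.63% against 60.8 ± 17.96%). The promoter of CYP94B3 was higher in 6 windows (chromosome 3, 17978251 to 17978350; 19.98 ± 1.19% against 0.885 ± 1.53%), those of the heat shock factor HSFB2B (chromosome 4, 7040901 to 7041000; 18.7 ± 6.41% against 55.01 ± 5.91%) and PR1 (chromosome 2, 6243551 to 6243650; 0.256 ± 0.444% against 21.45 ± 1.802%) lower. In all 60503 of 110663 tested windows passed, 30834 higher and 29669 lower. The majority turned with other thresholds, to 5133 and 6710 with at least 10 points and 82 and 170 with the stricter threshold. The authors' own calls over every deposited window were 44411 higher and 67973 lower. It also turned without WT R24 replicate 2 (20545 and 21030) or replicate 3 (20839 and 21439). The count was 37149, 38812 and 39309 without DM R24 replicates 1 to 3, and 39507 without WT R24 replicate 1. Of the windows called at both times, 44927 went the same way (23333 higher and 21594 lower, where 8743 and 9122 would be shared by chance) and 56 the opposite way; among CG-only windows these were 23878 and 2.

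The heat comparisons of methylation gave far fewer calls in the test used here than the genotype comparisons. The authors' own calls were 14167 higher and 43757 lower in DM heat, and 21267 higher and 125410 lower in WT heat. The median dispersion was 2.255 (DM heat) and 2.532 (WT heat), against 1.431 (C24) and 1.208 (R24) between genotypes. A low count here does not show that heat changed little. In DM (R24 against C24), 5108 of 57190 windows passed, 695 higher and 4413 lower, and in WT 5726 of 144739, 706 higher and 5020 lower. All of these calls ended with the dispersion held at 1 or above (0 in both), and 0 in DM and 1 in WT passed the stricter threshold. The methylation level in ONSEN windows was lower in both: ONSEN-f (chromosome 1, 18016701 to 18016800) was at 2.89 ± 0.708% at R24 and 36.3 ± 1.65% at C24 in DM (quasi-binomial adjusted p = 0.0138, n = 3), and in WT (chromosome 1, 18015401 to 18015500) at 3.89 ± 1.72% and 35.6 ± 2.59%. Called windows were lower in 7 of 8 copies in DM and 6 of 8 in WT. The CLSY1 promoter was lower in both, at 5.17 ± 5.13% against 38.7 ± 5.88% in DM (chromosome 3, 14761851 to 14761950) and 13.5 ± 3.87% against 40.3 ± 2.41% in WT (chromosome 3, 14761901 to 14762000). In DM the largest other losses were in promoters of AT5G56380 (chromosome 5, 22841051 to 22841150; 15.5 ± 10.7% against 66.4 ± 3.92%) and AT4G11300 (chromosome 4, 6874501 to 6874600; 8.80 ± 6.09% against 59.4 ± 8.18%), and the largest gain in that of AT1G40076 (chromosome 1, 15421051 to 15421150; 91.3 ± 4.57% against 44.1 ± 5.95%). In WT the largest losses were in the promoter of the transcription factor gene ATAF2 (chromosome 5, 2860551 to 2860650; 30.4 ± 13.9% against 85.4 ± 1.76%) and at WRKY43 (chromosome 2, 18957701 to 18957800; 14.8 ± 13.9% against 68.4 ± 2.80%).

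Of these calls, 1893 lower windows in DM and 2272 in WT lay in a block of chromosome 2 that resembles organelle DNA, and without the block and very deep windows 565 passed in DM (191 higher, 374 lower) and 517 in WT (199 higher, 318 lower). In all 1020 windows were called lower in both genotypes, 73 of them outside both the block and the very deep windows (34.9 by chance, Fisher's exact p = 2.5e-09). Overlapping neighbours count here as separate windows, so this p overstates the evidence for sharing. With replicate number as a block, DM had 1645 higher and 1906 lower windows. Leaving out any 1 library lowered the counts, and in DM the windows at an unadjusted p under 0.05 went from 25679 to between 17734 and 20856. Without DM R24 replicates 1, 2 and 3 there were 445 (219 higher, 226 lower), 436 (214 higher, 222 lower) and 516 (237 higher, 279 lower), and without DM C24 replicates 1, 2 and 3 308 (40 higher, 268 lower), 360 (47 higher, 313 lower) and 225 (35 higher, 190 lower). Leaving 1 out gave in WT 223, 394 and 364 without C24 replicates 1 to 3. Without WT R24 replicates 1, 2 and 3 the WT counts were 1009 (438 higher), 633 (417 higher) and 515 (356 higher). The majority of called windows thus turned to higher without replicate 2 or 3. Most of all tested windows stayed lower, with 123233 lower and 21391 higher without replicate 2, and 123220 and 21417 without replicate 3.

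Mean levels over the deposited windows, without the block and very deep windows, were lower in DM than in WT at C24 in CHG (17.1 ± 2.56% against 27.5 ± 7.02%, n = 3, exact permutation p = 0.1) and CHH (5.07 ± 0.986% against 11.2 ± 4.204%, exact p = 0.1), the smallest p this design allows. Over all windows of that table the CHH difference was -4.53 points, and -2.94 points without WT C24 replicate 1. In CG they were at 50.1 ± 2.94% and 59.6 ± 6.84% (exact p = 0.2). At R24 the genotypes did not separate (CHG 11.6 ± 1.59% against 15.1 ± 8.14%, exact p = 0.8). Over all windows of that table, DM minus WT was -1.14 (CG), -1.35 (CHG) and -1.297 (CHH) points, and 3.24, 1.18 and 0.308 points without WT R24 replicate 1; in CG it was 0.781 without DM R24 replicate 2. From C24 to R24, CHG and CHH went from 47.3 ± 2.15% to 36.03 ± 1.01% and from 13.8 ± 1.46% to 8.16 ± 0.509% in DM, and from 51.5 ± 3.84% to 37.4 ± 4.34% and from 16.5 ± 4.06% to 8.70 ± 3.53% in WT, each at exact p = 0.1. WT R24 replicate 1 stood apart from its group in CHH (12.96%, against 6.94 and 6.75% in the other replicates, over windows not methylated in CG only). The windows were chosen by the authors for a difference, so these are not genome-wide levels. That choice used the same samples and groups and favours the real grouping, so these exact p-values are not independent evidence for a difference.

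**Figure D3:**
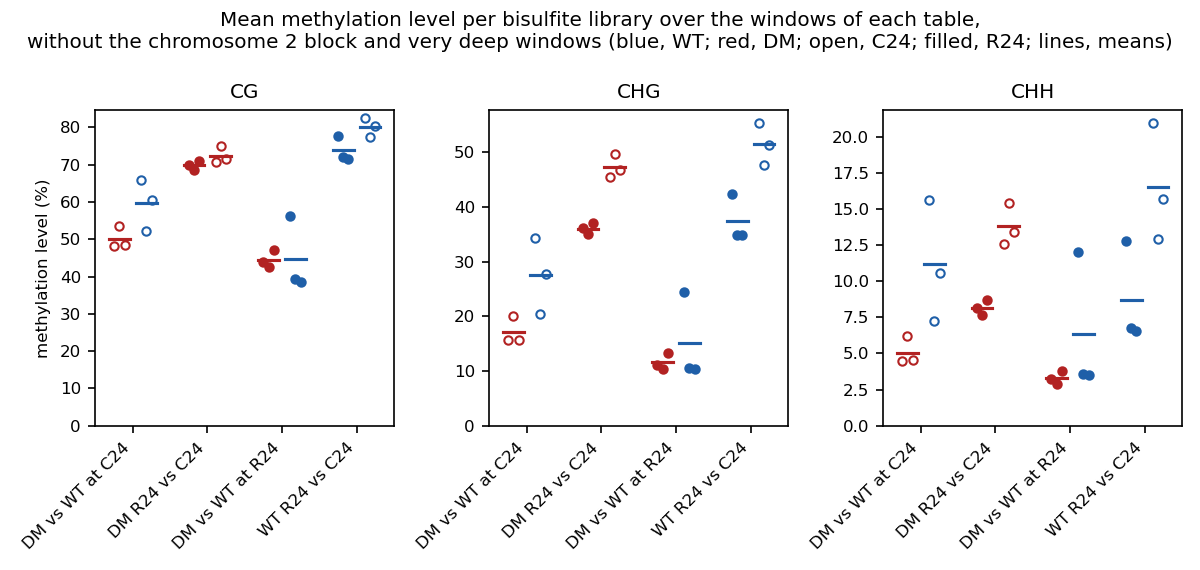
Mean CG, CHG and CHH methylation (percent) per bisulfite library over the windows of each deposited table, without the chromosome 2 block and very deep windows; blue is WT, red is DM, open points are C24, filled points R24, and lines are group means. In the WT heat table CHH is at 16.5% in C24 and 8.70% in R24, with 1 WT R24 library above the other 2.

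Genes with a called window in DM against WT at R24 changed expression slightly less often than the rest, 15.8% against 18.6% (odds ratio 0.821, Fisher's exact p = 1.6e-07, adjusted p = 6.4e-07 over 4 comparisons); with the stricter window threshold the odds ratio was 0.715 (p = 0.307). At C24 13 of the 15 genes that differed had a called window, MRD1 and FLC among them (odds ratio 2.39, Fisher's exact p = 0.382). In the heat comparisons the odds ratios were 1.09 in DM (Fisher's exact p = 0.191) and 1.03 in WT (exact p = 0.638). Among WT genes with a promoter window called in the heat comparison, expression was higher in 438 and lower in 95 of the less methylated, and higher in 178 and lower in 87 of the more methylated (odds ratio 0.444, Fisher's exact adjusted p = 3.4e-05 over 8 tests). In DM gene bodies the split was 152 and 20 against 84 and 37 (odds ratio 0.299, adjusted p = 0.000321). DM promoters (odds ratio 0.846, adjusted p = 0.662) and WT gene bodies (odds ratio 0.550, adjusted p = 0.0649) did not pass, and the genotype comparisons did not either (adjusted p of 0.662 to 1). Among all genes changed by heat, 11129 were higher and 4074 lower in WT, and 9989 and 5240 in DM. The heat window calls behind these splits ended with the dispersion held at 1 or above, and many lower ones lay in the chromosome 2 block. Splits without the block are not given, so no link between methylation loss and expression is drawn.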

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

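Of the tests of explanations in this part, those of WT RNA in the libraries labelled DM R0, of bisulfite conversion, of mixed DNA and of the chromosome 2 block were chosen only after the result was seen, and the rule that reads the range over library pairs for the mixed DNA was added after its value was seen.

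A test of the difference between the heat responses of the genotypes passed for 1277 genes at 0 h and 1521 genes at 24 h (limma), and at 0 h it rests on the libraries labelled DM R0. By list, camera gave a difference at 0 h for small heat shock proteins (adjusted p = 0.0141), light harvesting (7.26e-05), salicylic acid defence (0.0098), the cell cycle (0.0088), leaf senescence (0.0356), seed maturation (0.0124) and ONSEN (0.0124). At 24 h it gave one for small heat shock proteins (9.43e-05), light harvesting (4.95e-08), the cell cycle (0.000574) and root markers (0.00196). Rescaled, leaf senescence was at 0.0716. None of these lists held with an estimated correlation (adjusted p = 0.695 for light harvesting at 0 h and 0.928 at 24 h). Among genes with large changes in either genotype after recovery, the response was more positive in DM for ELI3-2 (1.94) and CYP76C2 (1.24) and more negative for ECS1 (-1.91), GER3 (-1.80), CA1 (-2.36) and CA2 (-2.60).

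The first pattern is the transcript of SDG25 and ATX1 in the libraries labelled DM R0, at 66.2% and 105% of the WT R0 level. WT RNA mixed into these libraries, or WT libraries under their label, would bring every other gene that is low in DM up by at least the mixed share. Of the 5 genes called lower in DM at both control times (MRD1, FLC, MAF5, SADHU3-2 and FLM), the highest share was 36.3% (FLM), and 10 of 10 gene and library pairs lay below SDG25 in the same library. Of genes called lower at 1 control time only, AT5G06865 (20.69 against 10.2 FPKM), AT2G44120 (53.05 against 63.92) and TAO1 (3.281 against 3.998) returned further, MAF4 in part (3.734 against 8.508), AT5G23155 stayed low (1.492 against 14.73) and CLE7 had no signal at R0 in either genotype. Mixing needs every gene with signal in WT R0 to return, while a gene can return without it. FLC, MAF5 and SADHU3-2 reached at most 12.86, 20.7 and 12.07% over library pairs, and SDG25 at least 26.91%, which argues against mixing as the whole cause. MRD1 and FLM reached at most 41.08 and 40.53%. For these 5 genes no library pair came near the WT R0 level, which argues against WT libraries under this label. Genomic DNA or general read-through is argued against by 7230 genes silent in all control libraries, whose median was 0.0001 FPKM in the libraries labelled DM R0. Heat-induced transcription through the mutated loci, which would be biological in part, stays open and was not tested, since the values are per gene and not per exon.

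The second pattern is the high CHH level of WT R24 replicate 1. Incomplete conversion would raise CHH in the unmethylated chromosome 2 block as much as elsewhere, but the block was at 0.484% against 0.361 and 0.352% in the other replicates, an excess of 0.128 points beside 6.10 points outside it, which argues against it. With WT C24 DNA mixed in, the library would lie as far toward C24 in CG as in CHH. It lay 15.1% of the way in CG of CG-only windows and 61.4% in CHH of other windows, and this ratio ran from 0.153 to 0.389 over library pairs. In the same other windows it lay 72.8% of the way in CG and 42.6% in CHG. In CG-only windows, from low levels, it lay 67.25% of the way in CHG and 119.5% in CHH. The depth of the chromosome 2 block in this library also lay between the other R24 libraries and C24 (values below). That does not separate mixing from a real difference. Mixing and a real difference of that plant pool therefore cannot be told apart with 3 libraries.

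The third pattern is the lower methylation at R24 in the chromosome 2 block, which resembles organelle DNA. Levels went from 4.82 ± 0.863% to 0.793 ± 0.192% in WT and from 2.84 ± 0.785% to 0.792 ± 0.121% in DM. The authors had called 5557 of these 5644 windows lower in WT and 5073 of 5181 in DM, so the direction follows from that choice. If more unmethylated organelle reads were counted there at R24, all calls would rise and methylated calls would not. Per nuclear call, all calls were 8.35-fold higher in WT and 4.17-fold in DM. The WT mean hides a spread. Scaled to a fixed number of nuclear calls, the block held 1972.9 calls in WT R24 replicate 1 and 5414.1 and 5875.9 in replicates 2 and 3. The WT C24 libraries held 374.3, 768.4 and 452.9 on that scale, which counts ONSEN windows as nuclear. The limits of the block were themselves set from where coverage was very high. Methylated calls moved by 0.39 (WT) and 0.27 (DM) on the log2 scale, group means near what this explanation needs. Over library pairs the methylated calls ran from -0.594 to 1.116 in WT and from -0.093 to 0.709 in DM, a wider range than these means show. Nuclear calls were those of the deposited windows outside the block, the ONSEN copies and very deep windows. A candidate explanation is thus a larger share of organelle DNA; whether the plants or the DNA extraction gave it stays open.

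For the windows called in each table, the authors had picked the windows by the real grouping, which fixes the outcome, so this count of splits excludes nothing. The 10 splits of 6 samples are also too few for a share under 0.05. The real split was 1 of 10 in each. The real count was 91271 (DM against WT at C24), 5108 (DM heat), 60503 (DM against WT at R24) and 5726 (WT heat), and the highest of the other splits gave 0, 0, 0 and 1.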

How the results depend on the processing

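The dispersion of at least 1, the test on logit levels, the window sets, the minimum of 10 points and the fits without both R0 libraries of a genotype were chosen after seeing the data; the other alternatives were planned. No named gene changed direction. For DM against WT at R24, differences in mean level changed sign without WT R24 replicate 1 (from -1.14 to 3.24 points in CG, -1.35 to 1.18 in CHG and -1.297 to 0.308 in CHH) or, in CG, without DM R24 replicate 2 (0.781). The majority of called windows changed side there and in WT heat, while most of all tested windows stayed lower in both. The odds ratios of methylation and expression in heat, which did not pass, were below 1 over every deposited window (0.980 in DM and 0.998 in WT).

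Counts of genes moved by more than 1.5 times as follows. With a pseudocount of 0.1, DM against WT gave 26 genes at C0 and 24 at C24, and with no filter 30 at C0. Rescaling gave 28 at C24, 751 for the interaction at 0 h, 4729 memory genes and 179 of them lower in DM (655 higher). Quantile normalisation gave 24 at C24, 5014 memory genes and 186 lower (771 higher). With an absolute log2 fold change of at least 1, heat gave 9132 (WT R0), 7152 (WT R24), 9670 (libraries labelled DM R0) and 7964 (DM R24) genes. DM against WT gave 1017 (R0, on that label) and 1011 (R24), and the interactions gave 664 (0 h) and 830 (24 h). Memory genes numbered 3341, with 48 lower (124 higher). Fewer genes pass by construction.

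With only the libraries compared in the limma fit, 0 genes passed for DM against WT at C0, C24 and R0 and for the interaction at 0 h (1307, 1843, 4113 and 3754 at an unadjusted p under 0.05), and 2577 for the interaction at 24 h. Without both WT R0 libraries the counts were 26 at C0, 28 at C24 and 2741 for the interaction at 24 h. With an estimated correlation 3 list tests passed in place of 66.

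For windows, an adjusted p under 0.01 with at least 25 points gave 585 (DM against WT at C24), 0 (DM heat), 252 (DM against WT at R24) and 1 (WT heat), and at least 10 points gave 17943, 1769, 11843 and 1663 in that order. Non-overlapping windows gave 45709, 2572, 30379 and 2800. The replicate block gave 23253 (C24) and 23371 (R24). Dispersion of at least 1 gave 51857 (C24) and 0 in both heat comparisons, where quasi-binomial calls at an unadjusted p under 0.05 had been 25679 (DM) and 53454 (WT). A moderated test on logit levels, written in the manner of limma but not run with it, gave 9308 (DM heat) and 11893 (WT heat). Without the block and very deep windows 565 (DM heat) and 517 (WT heat) passed. Mean levels then differed by -2.63 (CG) and -5.64 (CHH) points in DM and by -6.19 (CG) and -14.1 (CHG) in WT. Shared windows were 137 (genotype) and 0 (heat) with the stricter threshold and 73955 and 24843 over every deposited window. The odds ratio of methylation and expression was 1.31 (Fisher's exact p = 0.0220) for gene bodies in DM heat and 0.715 (exact p = 0.307) at R24 with the stricter threshold. Apart from the smaller sets of windows or samples, the cause was not tested.

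Leaving out 1 library gave 8 to 12 genes for DM against WT at C0, 1659 to 8316 at R0 and 1663 to 2364 at R24, 123 to 5644 and 448 to 1072 for the interactions at 0 h and 24 h, and 145 to 616 memory genes lower in DM. The lone library of a group is assumed to vary like the other groups. Windows ranged over 49547 to 63442 (C24), 37149 to 42278 (R24), 225 to 516 (DM heat) and 223 to 1009 (WT heat).

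Of 172 named genes and comparisons, 171 passed; of 1996 alternative values 1787 kept direction and side of the threshold and 209 kept only the direction. Calls were lost somewhere for 71, of which 37 on leaving out 1 library. With a pseudocount of 0.1 calls were lost for CYP71A12, JAZ8, NRT2.1 and PYK10 (R24), HSP17.6II, HSP21, ORE1, SAG13 and WRKY38 (R0), SADHU3-2 (C24) and JRG21 (interaction at 24 h), at adjusted p of 0.0502 to 0.148. With no filter they were lost for CRU3 and TAO1 (C0), SADHU3-2 (C24), ORE1, SAG13 and WRKY38 (R0), CYP71A12, FT, HSP17.6A, ICL, MLS and PYK10 (R24), CRU3, FT, GSTU12 and MYB28 (interaction at 0 h) and BCAT4, JRG21, MAM1 and sks9 (interaction at 24 h), at 0.0586 to 0.144. Rescaling ended that of MYB28 (0.0515), and quantile normalisation those of FT (0.0503), HSP17.6A (0.06) and PYK10 (0.0912) at R24. A minimum of 5 FPKM and coverage minimums of 1, 5 and 20 moved no count by more than 1.5 times. A promoter of 1 kb was not run, since the deposited annotation gives no width.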

Other observations

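None of the tests in this part was chosen only after its result was seen, but the ONSEN levels had been seen before the ONSEN depths were tested, and the glucosinolate pathway was picked because CYP79F1, BCAT4 and MAM1 were among the lowest genes.

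Genes of the aliphatic glucosinolate branch were lower in DM at R24. CYP83A1 was at 14.6 FPKM in DM R24 and 100.3 FPKM in WT R24 (log2 fold change -2.86, limma adjusted p = 0.000331), with IPMI1 at -2.69, BASS5 at -2.39 and IMD1 at -2.34. Of 15 aliphatic genes picked apart from those named by the rule, these 4 included, 15 were lower (median -1.91), and of 8 indole genes CYP79B2 was higher (1.00) and MYB34 lower (-1.09), with a median of 0.23; the branches were not tested against each other. In WT heat (R24 against C24) 7 of the 15 were lower and 1 higher (median -0.62). At C24, 0 of the 15 passed in limma (median -0.15), and the interaction at 24 h was negative for 10 (median -1.73). The fall was there at the end of heat in the libraries labelled DM R0 (10 lower and 1 higher than in WT R0, median -1.17), so, as far as that label holds, it was not confined to recovery. Light harvesting genes were also lower in DM at R24 (24 of 25) and the root list higher (camera adjusted p = 0.00789), and a shift between tissues was not tested.

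Deposited windows of the ONSEN copies, whose transcripts rose with heat, had a lower methylation level at R24 while their DNA calls increased. Levels went from 26.7 ± 2.94% to 6.80 ± 3.34% in WT and from 23.3 ± 1.24% to 3.71 ± 0.241% in DM (SD, n = 3). The authors had called 260 of these 262 windows lower in WT and 235 of 238 in DM, from the same samples. The direction of the fall thus follows from that choice, and these are not levels of the whole copies. If extra unmethylated copies had been made, all calls would rise and methylated calls would stay. Per nuclear call, all calls were 3.34-fold higher in WT and 5.96-fold in DM. Methylated calls moved by -0.36 in WT and -0.07 in DM on the log2 scale as group means. Over library pairs the methylated calls ran from -0.839 to 0.209 in WT and from -0.192 to 0.054 in DM. Extra unmethylated ONSEN DNA is a candidate explanation for these levels, and loss of methylation at the resident copies was not separated from it. Reads may be shared among the copies.

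Windows methylated in CG only were called different between the lines without heat, since C24 seedlings were never heated (21124 windows higher and 20730 lower in DM). Of such windows called at both C24 and R24, 99.99% went the same way (23878 the same and 2 the opposite way). Windows not methylated in CG only did so in 99.74% (21049 and 54), so the match is not particular to CG-only windows. The called windows at the 2 times come from separate libraries, and sibling lines of each genotype were not available to tell a mutant effect from drift.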
